A study of Homo sapiens with 15 samples.

How the data were processed

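Poly(A)-selected RNA of MV-4-11 cells was sequenced in 15 libraries, 3 in each of 5 groups, and 1 table holds all of them. Per the labels' protocols, RNA was taken up in Trizol, checked on a Bioanalyzer, enriched with oligo(dT) beads, copied with random primers and sequenced on an Illumina HiSeq instrument. The genome build is not given in the sources used here, so no coordinates are printed, and the strand protocol is not stated. The growth protocol in the labels names RPMI as the medium and the design text names IMDM, and the conflict could not be settled.

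Per the submitters' processing notes, the tools used were fastp 0.18.0, HISAT2, StringTie 1.3.1, DESeq2 and edgeR; the notes given here do not say which step each made. Per the file headers, the table holds for each library a column of counts and a column of TPM. The deposited counts are expected counts: between 11.2% and 14.0% of the cells of a library were not whole numbers. The authors' TPM columns each sum to 1000000. The table has 20375 genes, of which 645 have no symbol; 20322 of the gene IDs are in the gene names table, and 19737 are protein-coding genes of GENCODE release 29, with 246 IDs not in that release. Every sample column was matched to a sample.

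The expected counts were rounded to whole numbers. Genes were kept with filterByExpr of edgeR 4.0.16, leaving 12448, and libraries were scaled by TMM (trimmed mean of M values). One robust quasi-likelihood model with a mean per group was fitted to the 15 libraries, with 10 residual degrees of freedom and a biological coefficient of variation of 3.17%. There were 8 contrasts: each cytarabine dose against control, 5 µM against 2 µM cytarabine, each switch to FL-Fc-DM1 against the same cytarabine dose for 4 days, each switched group against control, and the difference between the switches, called the dose interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 are called changed; adjusted p values of genes are from edgeR. CPM values are TMM-scaled counts per 1000000, given with the standard deviation (SD) of 3 libraries, and log2 fold changes with the standard error (SE) of the fit.

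Before the data were examined, 29 gene lists with 497 memberships were fixed from general knowledge, and all members are in the file. Some genes belong to several lists, so the results of such lists are not independent. They cover DNA replication, mitosis and G2/M, G1/S E2F targets, homologous recombination and Fanconi anaemia, replication-dependent histones, tubulins, ribosome biogenesis and MYC targets, interferon-stimulated genes, NF-kB and inflammatory genes, STAT5 targets, MAPK output genes, the integrated stress response, endoplasmic reticulum chaperones, cholesterol synthesis, the BCL2 family, cytarabine transport and metabolism, conjugate uptake with lysosome and efflux, nuclear-encoded oxidative phosphorylation, mitochondrially encoded RNAs and KMT2A-rearranged leukaemia genes. The other lists are markers of monocytes and macrophages, neutrophil granules, stem and progenitor cells, erythroid cells, megakaryocytes and platelets, T and NK cells, B cells, and epithelial cells and fibroblasts. 1 more list is not reported here. Of the 29, 26 had at least 3 tested members and were tested with camera of limma 3.58.1 at its preset correlation between genes of 0.01, with adjustment over the lists of a contrast; the erythroid, T and NK cell, and epithelial and fibroblast lists are given as values. Each list was also tested with a correlation estimated from the data and with fry, which tests whether members move on balance one way.

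Genes were named by a rule. For the cytarabine contrasts against control and the switches, the 5 highest and 5 lowest log2 fold changes qualify among called genes with a symbol, at least 10 CPM in the higher group and no overlap between the libraries of the groups compared. Up to 4 members of each list with the smallest adjusted p also qualify (2 as values where none is called), and FLT3, CDKN1A, MDM2, MYC, MKI67, TUBB and TUBA1B always. For the other 4 contrasts the 3 highest and 3 lowest qualify. Group levels, and values of these genes in a contrast other than the one that qualified them, are given for context.

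The sharing of changes between doses was set against 20 simulations with no effect in which both doses share the 3 control libraries. Shares of counts were compared with exact permutation tests. Alternatives were relative log expression (RLE) scaling, no filter and a strict filter of 5 CPM, DESeq2 1.42.0, a replicate block, each library left out in turn, fits of only the groups compared, an absolute log2 fold change of at least 1 and limma-trend. The planned limma-trend fit on log2(FPKM + 1) was run on log2(TPM + 1), since the file holds TPM and no FPKM; this TPM fit changes scaling, pseudocount and test together. The residual profiles of same-number libraries correlated above 0.1 in every pair in 1 of 10 pairs of groups, 2 µM with 5 µM cytarabine (0.18, 0.17 and 0.13); adding a block for the number there moved the calls by less than 1.5 times and ended none of the list calls. R 4.3.3 was used for the fits and Python 3.11.15 with matplotlib 3.10.9 for the plots.

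The fits were tested on simulated counts for 2 µM cytarabine against control with 12448 genes, of which 200 were changed, 50 at each fold. edgeR recovered 52%, 70%, 88% and 94% of the genes changed 1.2-, 1.5-, 2- and 4-fold with 10 false calls. DESeq2 recovered 48%, 68%, 88% and 94% with 5 false calls, and limma-trend 50%, 72%, 90% and 92% with 10. Of a list of raised genes and a list of unchanged genes, camera called only the raised list. The simulated genes varied independently and few were changed, while 68.9% of genes were called in the real contrast. The simulation therefore cannot test the scaling where most genes change, or camera where genes are correlated.

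Library totals were 13588481 to 17447107 counts in 14 libraries and 30421150 in replicate 2 of 2 µM cytarabine. A count of 3, the upper limit that a count of 0 allows, is 0.0986 to 0.221 CPM; such floors cover counting error only. There are no spike-ins, so every level is relative to the other RNAs of its library. The labels do not say whether the 3 libraries of a group come from separate cultures, and the p-values measure only the spread between these samples, which may be technical. The switch takes cytarabine away and adds FL-Fc-DM1 at the same time, and the series has no group with removal alone or FL-Fc-DM1 alone. Counts of near-identical genes such as tubulin and histone paralogs depend on how reads were assigned to them.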

Results

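MV-4-11 is a myelomonocytic leukaemia line with a KMT2A rearrangement and an internal tandem duplication in FLT3. RNA was measured in 5 groups of 3 libraries: control cells after 4 days, cells after 4 days in 2 µM or 5 µM cytarabine, and cells kept for 3 days in either dose and then for 24 hours in 1 nM FL-Fc-DM1 without cytarabine. FL-Fc-DM1 is named as a conjugate of the ligand of the receptor FLT3, joined to an antibody Fc part, with DM1, a maytansinoid that binds tubulin. Library totals ranged from 13588481 to 30421150 counts, and 13976 to 14930 genes had counts in a library. Values are relative to the other RNAs of each library, and the switch combines the removal of cytarabine with the addition of FL-Fc-DM1.

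The 3 libraries of each group lay close together and the 5 groups apart in a principal component analysis. The first component held 44.7% of the variance and set control cells apart from the 4 treated groups. The second held 29.7% and set the cytarabine groups, at positive values, apart from the FL-Fc-DM1 groups, at negative values. Libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.66 to 4.54 over the 15 pairs.

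**Figure D1:**
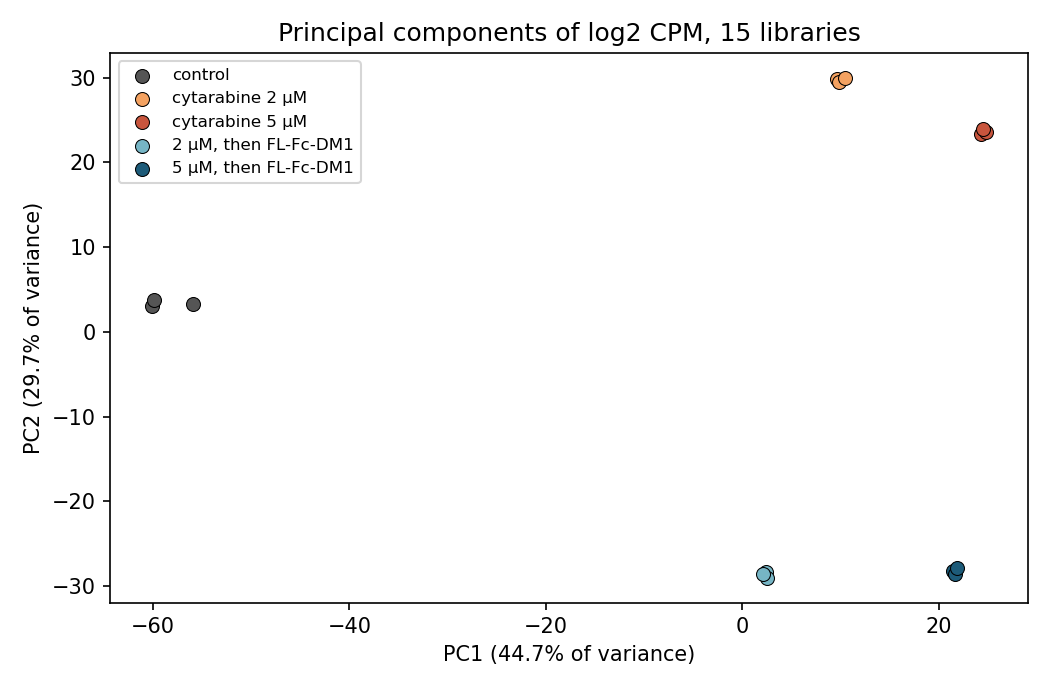
Principal components of log2 CPM in the 15 libraries, 3 per group. Each point is a library, and the axes give the share of variance.

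The first comparison asked which transcripts differ between cells in cytarabine, a nucleoside analogue that is built into DNA and stalls its synthesis, and control cells. Monocyte and macrophage markers, interferon-stimulated genes and NF-kB targets were higher at both doses, and ribosome biogenesis genes and MYC were lower. ITGAM (ENSG00000169896), the integrin chain CD11b of mature myeloid cells, was at 4.16 ± 1.21 CPM in control (SD, n = 3) and rose to 47.6 ± 0.563 at 2 µM and 77.0 ± 1.94 at 5 µM. MYC (ENSG00000136997), a transcription factor of growth, fell from 351 ± 7.81 CPM to 115 ± 1.54 and 94.4 ± 0.683. BCL2 (ENSG00000171791), an inhibitor of apoptosis, fell from 242 CPM to 96.0 and 83.5 CPM.

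Of 12448 genes, 4479 rose and 4100 fell at 2 µM, and 4654 rose and 4251 fell at 5 µM. At least 2-fold changes were 1044 up and 303 down at 2 µM, and 1267 up and 440 down at 5 µM. A limma-trend fit on log2(TPM + 1), the TPM fit below, changes scaling, pseudocount and test together. It gave 4810 up and 2699 down at 2 µM, and 5274 up and 2889 down at 5 µM, with the median of all genes at 0.10 and 0.13 (log2), against 0.03 and 0.02 with TMM and edgeR. The libraries of the groups compared did not overlap for 8803 genes at 2 µM and 9069 at 5 µM, where chance gives 10% of genes.

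The highest named changes included ABCG1 (ENSG00000160179), a cholesterol exporter, with a log2 fold change of 4.46 ± 0.15 (SE) at 2 µM and 4.69 ± 0.15 at 5 µM. GPNMB (ENSG00000136235), a glycoprotein of macrophages and their lysosomes, rose by 4.20 ± 0.13 and 5.22 ± 0.12, and S100A9, a calprotectin subunit of myeloid cells, by 4.05 and 4.65. SUCNR1, the succinate receptor, rose by 3.80 ± 0.09 at 2 µM, and LRP1, an endocytic receptor, by 3.75 ± 0.08. At 5 µM the immune receptor LILRA5 (ENSG00000187116) rose by 5.20 ± 0.23 and the metalloprotease ADAM28 by 4.68 ± 0.14. The lowest by the naming rule was IGLL1 (ENSG00000128322), part of the surrogate light chain of B-cell precursors, at -3.81 ± 0.17 and -4.99 ± 0.22. PRDM8 was at -3.61 and -3.86, HPDL at -2.49 and -3.09 and the adhesion protein SDK2 at -2.27 and -2.89. MT1G, a metallothionein, was at -2.32 at 2 µM, and PRSS57, a serine protease of neutrophil granules, at -2.53 at 5 µM.

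Of 21 tested monocyte and macrophage markers, 18 rose and none fell at either dose (median 1.34 and 1.67, camera adjusted p = 1.1e-19 and 9.73e-23). Examples are ITGAX, the integrin chain CD11c, at 3.20 and 3.36, and CD68, a lysosomal protein of macrophages, at 1.92 and 2.53. TLR4, the receptor for lipopolysaccharide, rose by 1.34 and 1.67. Of 16 genes for conjugate uptake, lysosome and efflux, 15 rose and 1 fell at 2 µM, and 14 rose and 1 fell at 5 µM (median 0.59 and 0.71, camera adjusted p = 1.92e-08 and 2.38e-09). The lysosomal proteases CTSB and CTSD each rose by 1.5 at 2 µM, and by 1.87 and 1.93 at 5 µM. The Fc receptors FCGR1A and FCGR2A rose by 1.14 and 1.05 at 2 µM and by 1.03 and 1.29 at 5 µM.

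Of 24 interferon-stimulated genes, 20 rose and 1 fell at 2 µM, and all 24 rose at 5 µM (median 1.43 and 1.99, camera adjusted p = 1.42e-06 and 9.18e-13). IFI6 rose by 3.21 and 4.01, OAS1, which senses double-stranded RNA, by 2.60 and 3.79, and STAT2, a transcription factor of the interferon response, by 0.98 and 1.22. Of 16 NF-kB and inflammatory genes, 15 rose and 1 fell at 2 µM, and 15 rose and none fell at 5 µM (median 1.05 and 1.2, camera adjusted p = 6.31e-05 and 1.33e-04). The chemokine CCL2 rose by 3.02 and 3.66, and the adhesion molecule ICAM1 by 2.25 and 2.44.

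All 20 ribosome biogenesis genes and MYC targets fell at both doses (median -0.88 and -1.04, camera adjusted p = 2.76e-30 and 1.29e-26). NPM1, a nucleolar chaperone, was at -0.81 and -0.89, NCL, a nucleolar RNA-binding protein, at -0.90 and -1.07, and ODC1, an enzyme of polyamine synthesis, at -1.32 and -1.43. Of 14 endoplasmic reticulum chaperones, 1 rose and 10 fell at both doses (median -0.44 and -0.46, camera adjusted p = 1.49e-05 and 3.53e-04). HYOU1 was at -0.91 and -0.89, HSPA5 at -0.72 and -0.62, and XBP1, a transcription factor of the unfolded protein response, at -0.59 and -0.87. Of 18 cholesterol synthesis genes, 1 rose and 14 fell at 2 µM, and 1 rose and 15 fell at 5 µM (median -0.35 and -0.42, camera adjusted p = 3.28e-05 and 5.77e-05). HMGCS1, an early enzyme of the pathway, was at -1.11 and -1.24, CYP51A1 at -0.97 and -1.10, and the member that rose, the sterol carrier STARD4, at 0.87 and 0.97. Of 21 nuclear-encoded genes of oxidative phosphorylation, none rose and 11 fell at 2 µM, and 1 rose and 13 fell at 5 µM (median -0.20 and -0.25, camera adjusted p = 0.0309 and 0.00861), with adjusted p = 0.564 and 0.524 with an estimated correlation. Without control replicate 3 the adjusted p of this list at 2 µM was 0.0648.

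Of 21 G1/S E2F targets, 16 rose and 4 fell at 2 µM (median 0.38, camera adjusted p = 7.21e-05), and 12 rose and 5 fell at 5 µM (median 0.23, camera adjusted p = 0.108). CCNE2 (ENSG00000175305), cyclin E2 of S-phase entry, rose by 1.74 and 1.57, the repressor E2F8 by 1.10 and 0.97 and the ribonucleotide reductase subunit RRM2 by 0.62 and 0.43, and UHRF1, a reader of methylated DNA, was at -0.59 and -0.80. Of 20 genes of homologous recombination and Fanconi anaemia, 17 rose and 1 fell at 2 µM, and 15 rose and 1 fell at 5 µM (median 0.41 and 0.35, camera adjusted p = 2.48e-05 and 0.00204), with adjusted p = 0.0854 and 0.222 with an estimated correlation. RAD51AP1 rose by 0.94 and 0.86, the nuclease EXO1 by 0.76 and 0.56 and BRCA2 by 0.67 and 0.86. Of 30 DNA replication genes, 18 rose and 5 fell at 2 µM (median 0.15, adjusted p = 0.319; 20 and 1 in the TPM fit), and 7 rose and 11 fell at 5 µM (median -0.05, adjusted p = 0.42), where the TPM fit gave 13 up, 5 down and a median of 0.07. Of 30 mitosis and G2/M genes, 13 rose and 11 fell at 2 µM (median -0.01, adjusted p = 0.68; 14 up, 7 down and a median of 0.09 in the TPM fit), and 16 rose and 7 fell at 5 µM (median 0.13, adjusted p = 0.338). MKI67, a marker of proliferation, rose by 0.23 ± 0.03 and 0.20 ± 0.03.

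CDKN1A, the cell cycle inhibitor p21, rose by 0.63 ± 0.20 at 2 µM (adjusted p = 0.0166) and 0.85 ± 0.20 at 5 µM (adjusted p = 0.00318). The call at 2 µM was lost without control replicate 2 (adjusted p = 0.0641), without control replicate 3 (0.0637), without replicate 1 of 2 µM cytarabine (0.0561) and in a fit of these groups alone (0.0606). MDM2, a ubiquitin ligase, was at -0.61 ± 0.05 and -0.56 ± 0.05.

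Of 12 tested KMT2A-rearranged leukaemia genes, 2 rose and 6 fell at 2 µM, and 3 rose and 6 fell at 5 µM (median -0.07 and -0.07; 4 up and 5 down with 0.005, and 6 up and 4 down with 0.05, in the TPM fit; camera adjusted p = 0.0184 and 0.0389), with adjusted p = 0.112 and 0.222 with an estimated correlation. HOXA9, a transcription factor of blood progenitors, was at -0.61 and -0.59, and CDK6, a kinase of G1, at -0.74 and -0.85. Of 14 BCL2 family genes, 6 rose and 4 fell at 2 µM, and 5 rose and 5 fell at 5 µM (adjusted p = 0.829 and 0.812). The inhibitor of apoptosis BCL2A1 rose by 4.09 and 4.73, BMF, which promotes apoptosis, by 1.21 and 1.52, and BCL2L11, which encodes BIM, by 0.57 and 0.60. FLT3 (ENSG00000122025) rose by 0.23 ± 0.03 at 2 µM, from 594 to 698 CPM, and was at 0.05 ± 0.03 at 5 µM (adjusted p = 0.0978; called at 0.19 in the TPM fit).

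Other lists were not called at either dose; a replicate block added neutrophil granule markers (down, adjusted p = 0.0326 and 0.0379) and, at 2 µM, integrated stress response genes (down, 0.0492). Of 14 integrated stress response genes, 5 rose and 8 fell at both doses (adjusted p = 0.0527 and 0.145); the cystine carrier SLC7A11 rose by 1.79 and 2.70, and asparagine synthetase, ASNS, was at -1.53 and -1.52. Of 14 genes of cytarabine transport and metabolism, 8 rose and 5 fell at 2 µM, and 7 rose and 5 fell at 5 µM (adjusted p = 0.402 and 0.756). Of 14 MAPK output genes, 8 rose and 3 fell, and 7 rose and 4 fell (adjusted p = 0.833 and 0.759; at 5 µM the median was 0.40, the mean 0.21 and the camera direction down), with DUSP6, a phosphatase of ERK, at 0.96 and 0.66. Of 12 STAT5 targets, 3 rose and 5 fell, and 4 rose and 4 fell (adjusted p = 0.991 and 0.584), with the interleukin-2 receptor chain IL2RA at 1.0 and 1.36. Of 10 tubulins, 2 rose and 4 fell at 2 µM (median 0.07, mean 0.12, camera direction down, adjusted p = 0.564; 5 up in the TPM fit), and 3 rose and 6 fell at 5 µM (median -0.17, mean 0.007, adjusted p = 0.372). TUBB (ENSG00000196230), the main beta-tubulin here, was at 0.04 ± 0.03 (adjusted p = 0.15) and -0.14 ± 0.03, and the alpha-tubulin TUBA1B at -0.09 ± 0.03 and -0.24 ± 0.03. In the TPM fit TUBB was called higher at 2 µM (0.14) and not called at 5 µM, and TUBA1B at 2 µM turned to 0.0079. Of 9 replication-dependent histones, none rose and 3 fell at 2 µM (median 0.09, mean -0.28, adjusted p = 0.503), and 6 rose and 2 fell at 5 µM (median 0.83, adjusted p = 0.682); these mRNAs end without a poly(A) tail, so poly(A) selection misses most of them.

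Markers of other cell types were also listed. Of 8 neutrophil granule markers, 3 rose and 3 fell at both doses (mean -0.19 and -0.25, camera direction down, adjusted p = 0.0717 and 0.0814; medians within 0.09 of 0, above 0 in the TPM fit); the granule proteases CTSG and ELANE were at -2.24 and -1.28 at 2 µM and -2.51 and -1.52 at 5 µM. Of 6 stem and progenitor markers, 2 rose and 3 fell at both doses (adjusted p = 0.535 and 0.407), with medians of -0.13 and -0.31, means of 0.24 and 0.19 and a camera direction of down. All 6 tested B cell markers rose at both doses (adjusted p = 0.361 and 0.393). Summed levels here cover all members of a list, tested or not. For the 11 B cell markers the sum was 3.92 ± 0.581 CPM in control, 10.2 ± 0.249 at 2 µM and 11.2 ± 1.4 at 5 µM. Of 5 tested megakaryocyte and platelet markers, 4 rose and none fell at both doses (adjusted p = 0.388 and 0.393), with 5.47, 12.8 and 13.7 CPM summed over all 9. The T and NK cell list had 2 tested members, and its 12 members summed to 18.3, 57.0 and 56.5 CPM, nearly all from NKG7, a granule protein of cytotoxic cells. The erythroid list summed to 13.1, 14.3 and 10.9 CPM, and the epithelial and fibroblast list to 5.63, 4.93 and 4.55 CPM. Mitochondrially encoded RNAs held 4.59 ± 0.13% of counts in control, 4.96 ± 0.26% at 2 µM and 4.90 ± 0.15% at 5 µM (exact permutation p = 0.1 for each dose, the smallest possible); 5 of 13 rose and 1 fell at 2 µM, and 5 rose and 2 fell at 5 µM (adjusted p = 0.829 and 0.962). Counts adjusted over the list alone were the same as those above except for E2F targets (13 up), chaperones (2 up), mitosis (8 down) and STAT5 targets (3 up) at 5 µM and for MAPK genes (4 down) at 2 µM.

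**Figure D2:**
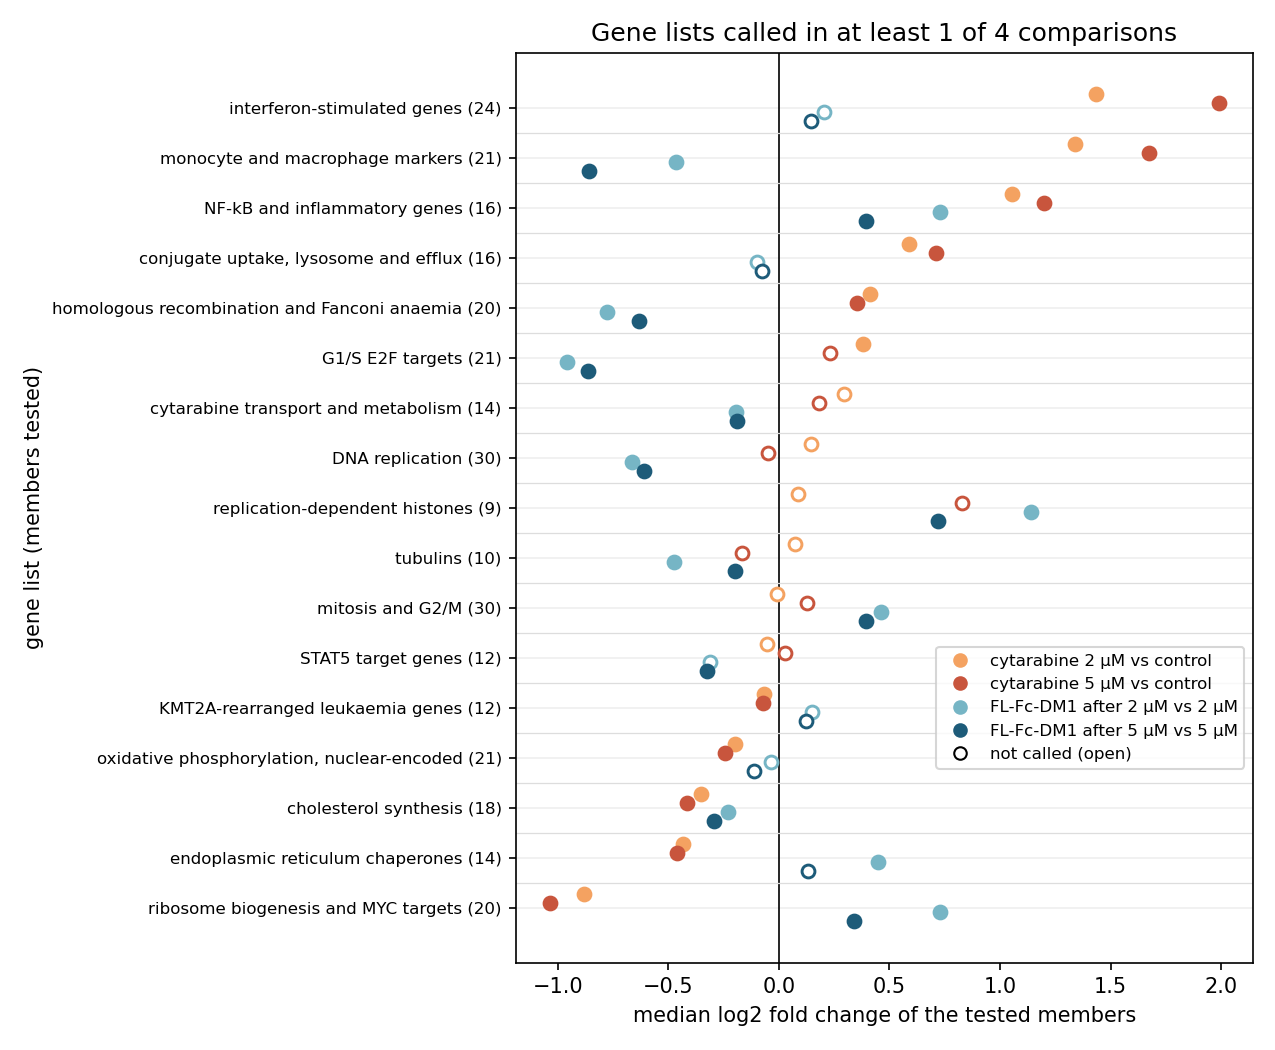
Median log2 fold change of the tested members of each gene list called in any of the 4 comparisons shown, 3 libraries per group. Filled points are lists called by camera at its preset correlation, and open points are lists not called. In the limma-trend fit on log2(TPM + 1) the medians of DNA replication at 5 µM against control, mitosis and STAT5 targets at 2 µM against control, and KMT2A-rearranged leukaemia genes at both doses against control change sign.

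The second comparison asked what the higher dose adds. Interferon-stimulated genes and monocyte markers were higher in 5 µM than in 2 µM cytarabine, and DNA replication and E2F genes were lower. MX1, an antiviral GTPase, rose by 1.38 ± 0.12, IFIT2, an interferon-induced RNA-binding protein, by 1.3 ± 0.10 and the metalloprotease ADAMDEC1 by 1.29 ± 0.08. Among called genes with at least 10 CPM in the higher group and no overlap between libraries, the lowest were CSPG4, PRSS57 and GNG7. CSPG4, a cell surface proteoglycan, was at -0.83 ± 0.06, PRSS57 at -0.77 ± 0.08 and GNG7, a G-protein subunit, at -0.71 ± 0.11. In all, 1256 genes rose and 1018 fell, with 55 up and 3 down at least 2-fold; the TPM fit gave 750 up and 291 down.

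Of 24 interferon-stimulated genes 18 rose and none fell, or 22 and none over the list alone (median 0.66, camera adjusted p = 1.43e-34). Of 21 monocyte and macrophage markers 12 rose and none fell, or 14 and 2 when adjusted over the list alone (median 0.42, camera adjusted p = 1.94e-15). None of 30 DNA replication genes rose and 24 fell, or 28 over the list alone (median -0.15, camera adjusted p = 3.36e-15), and 15 of 21 E2F targets fell (median -0.14, camera adjusted p = 2.33e-10). Of 30 mitosis genes 18 rose and none fell, or 20 over the list alone (median 0.12, camera adjusted p = 2.64e-11). Histones rose in 6 of 9 members (median 0.83, camera adjusted p = 1.14e-06), lysosome and uptake genes in 7 of 16 with 1 lower, or 10 and 2 over the list alone (adjusted p = 5.83e-05), and STAT5 targets in 5 of 12, or 6 over the list alone (adjusted p = 0.0135). Ribosome biogenesis genes fell in 7 of 20, or 10 over the list alone (camera adjusted p = 0.00172; adjusted p = 0.0802 with an estimated correlation) and oxidative phosphorylation genes in 6 of 21, or 8 over the list alone (camera adjusted p = 0.00639; adjusted p = 0.419 with an estimated correlation). MAPK output genes, 3 up and 6 down, or 4 and 7 over the list alone, had a median of -0.25, a mean of 0.01 and a camera direction of down (adjusted p = 0.0462; adjusted p = 0.122 with an estimated correlation and 0.0509 with RLE scaling). This call was also lost without replicate 1 of 2 µM (adjusted p = 0.0733) and without replicate 2 or 3 of 5 µM cytarabine (0.0594 and 0.061). In the TPM fit fewer members were called: 16 interferon, 8 monocyte, 16 mitosis, 4 histone, 4 lysosome and 4 STAT5 genes rose, and 8 DNA replication, 6 E2F, 2 ribosome biogenesis, 1 oxidative phosphorylation and 3 MAPK genes fell. The mitochondrial share differed by -0.06 points (exact permutation p = 0.8).

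The third comparison asked what differs between cells moved to FL-Fc-DM1 for the last 24 hours and cells left in cytarabine for 4 days. Genes of S-phase entry and DNA replication fell, while most mitosis and ribosome biogenesis genes were higher after both doses. NF-kB targets were higher on balance, with 11 up and 1 down after 2 µM, and 8 up and 6 down after 5 µM. CCNE2 went from 181 ± 6.02 CPM to 18.2 ± 1.25 after 2 µM, and from 161 ± 9.83 to 17.6 ± 1.03 after 5 µM (SD, n = 3). CCNB1, the mitotic cyclin B1, rose from 182 to 431 CPM and from 211 to 412 CPM. TUBB went from 2082 to 1062 CPM and from 1834 to 1020 CPM.

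After 2 µM, 3988 genes rose and 4057 fell, with 288 up and 613 down at least 2-fold. After 5 µM, 3410 rose and 3589 fell, with 256 up and 420 down at least 2-fold. The TPM fit gave 2794 up and 4045 down after 2 µM, and 2642 up and 3246 down after 5 µM. The highest by the naming rule were BIRC3 (ENSG00000023445), an inhibitor of apoptosis and NF-kB target, at 3.15 ± 0.12 after 2 µM, IL4I1 (ENSG00000104951), an amino acid oxidase of myeloid cells, at 2.92 ± 0.09, the complement protein C3 at 2.57 ± 0.09 and CYP1B1, a cytochrome P450, at 2.55 ± 0.14. MYOM1, a muscle M-band protein, rose by 2.47 and 2.42, and after 5 µM DOCK4, an activator of Rac, rose by 2.49, TIMM23B-AGAP6 by 2.21, PALD1 (ENSG00000107719) by 2.12 and BIRC3 by 2.12. TIMM23B-AGAP6 is a read-through of neighbouring genes, and its counts depend on how their shared reads were assigned. The lowest by that rule after both doses were FAM111B (ENSG00000189057), a serine protease, at -3.51 and -3.12, CCNE2 at -3.31 and -3.19 and the cytokine receptor chain IL31RA at -2.59 and -2.73. The synaptic vesicle protein SV2A was at -2.86 and SUCNR1 at -2.82 after 2 µM, and LILRA5 at -4.34 and the transglutaminase TGM2 at -2.74 after 5 µM.

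Of 21 G1/S E2F targets 1 rose and 20 fell after both doses (median -0.96 and -0.86, camera adjusted p = 2.39e-43 and 1.11e-51). E2F8 was at -2.39 and -2.07, CLSPN, a replication checkpoint mediator, at -1.64 and -1.64, and TYMS, thymidylate synthase, at -1.4 and -1.26. All 30 DNA replication genes fell (median -0.66 and -0.61, camera adjusted p = 5.78e-26 and 9.03e-28). The clamp PCNA was at -1.02 and -0.83 and the helicase subunit MCM4 at -0.68 and -0.72. Of 20 homologous recombination and Fanconi anaemia genes 1 rose and 18 fell after both doses (median -0.78 and -0.63, camera adjusted p = 3.9e-20 and 5.57e-20), with BRIP1 at -1.67 and -1.27 and EXO1 at -1.42 and -1.29. The larger KEGG pathways of these processes moved less. Their medians were -0.24 for homologous recombination and -0.18 for Fanconi anemia after 2 µM, and -0.16 for both after 5 µM. Of 14 genes of cytarabine transport and metabolism 6 rose and 7 fell after 2 µM (median -0.19, mean -0.42, camera adjusted p = 1.67e-04), and 2 rose and 7 fell after 5 µM (median -0.19, camera adjusted p = 1.34e-06). The nucleoside carrier SLC29A1 was at -1.12 and -1.26 and RRM1 at -0.87 and -0.86. RRM1, RRM2 and TYMS are also among the E2F targets above, so part of this fall is counted in both lists. MKI67 was at -0.52 ± 0.03 and -0.39 ± 0.03.

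Of 30 mitosis and G2/M genes 21 rose and 8 fell after both doses (median 0.46 and 0.39, camera adjusted p = 8.69e-12 and 1.22e-10). CDC20 (ENSG00000117399), an activator of the anaphase-promoting complex, rose by 1.55 and 1.07, CCNB1 by 1.24 and 0.97 and the mitotic kinase PLK1 by 1.19 and 0.89. All 9 histones rose (median 1.14 and 0.72, camera adjusted p = 0.00322 and 0.00991), with H2AC6 at 1.62 and 1.08; paralogs and poly(A) selection limit this group. Of 10 tubulins 2 rose and 5 fell after 2 µM (median -0.48, camera adjusted p = 0.00208; adjusted p = 0.128 with an estimated correlation), and none rose and 6 fell after 5 µM (median -0.20, camera adjusted p = 5.04e-05). TUBB was at -0.97 ± 0.03 and -0.85 ± 0.03, TUBA1B at -0.64 ± 0.03 and -0.70 ± 0.03, TUBA1A at -0.89 and -0.72 and TUBA4A at -1.19 and -1.37.

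All 20 ribosome biogenesis genes rose after 2 µM, and 18 rose and 1 fell after 5 µM (median 0.73 and 0.34, camera adjusted p = 3.19e-23 and 1.38e-10). ODC1 rose by 1.46 and 1.45 and UTP20, of the small subunit processome, by 1.14 and 0.66; MYC rose by 0.48 ± 0.03 and 0.36 ± 0.04. Of 16 NF-kB and inflammatory genes 11 rose and 1 fell after 2 µM, and 8 rose and 6 fell after 5 µM (median 0.73 and 0.39, camera adjusted p = 8.13e-07 and 0.00235). NFKBIA, the inhibitor of NF-kB, rose by 1.34 and 0.91, NFKB2 by 1.2 and 1.10 and NFKB1 by 0.92 and 0.72. Of 14 endoplasmic reticulum chaperones 11 rose and 2 fell after 2 µM (median 0.45, camera adjusted p = 6.89e-05), with HSPA5 at 0.72, and 6 rose and 3 fell after 5 µM (median 0.13, adjusted p = 0.272).

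Of 21 monocyte and macrophage markers 4 rose and 12 fell after 2 µM (median -0.47, camera adjusted p = 0.00948; adjusted p = 0.0524 with an estimated correlation), and 5 rose and 12 fell after 5 µM (median -0.86, camera adjusted p = 1.68e-04). ITGAX was at -1.11 after 2 µM and ITGAM at -1.36 after 5 µM, TLR4 at -0.85 and -0.88 and FCGR1A at -0.80 and -0.86, while the membrane protein MS4A7 of macrophages rose by 1.01 and 1.3. Summed over all 24 list members, the level went up from 3623 to 3884 CPM after 2 µM, as did the most abundant member. After 5 µM the sum went down from 4906 to 4600 CPM. Of 18 cholesterol synthesis genes 5 rose and 11 fell after 2 µM (median -0.23, camera adjusted p = 0.0251; adjusted p = 0.14 with an estimated correlation), and 2 rose and 12 fell after 5 µM (median -0.29, camera adjusted p = 1.11e-04). STARD4 was at -1.54 and -1.54 and FDFT1, squalene synthase, at -0.56 and -0.49. Of 12 STAT5 targets 3 rose and 5 fell after 2 µM (adjusted p = 0.41), and 1 rose and 7 fell after 5 µM (median -0.32, camera adjusted p = 0.00493), with the kinase PIM1 at -0.58 and -1.0 and IL2RA at -0.73 and -1.32.

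CDKN1A was at -0.55 ± 0.20 (adjusted p = 0.0324) and -0.72 ± 0.20 (adjusted p = 0.0103), and MDM2 was at 0.11 ± 0.05 (adjusted p = 0.0352) and 0.04 ± 0.05 (adjusted p = 0.485). After 2 µM, the CDKN1A call was lost without any 1 of 5 libraries, replicates 1 and 3 of 2 µM cytarabine (adjusted p = 0.102 and 0.0616) and replicates 1, 2 and 3 of the switched group (0.0522, 0.0875 and 0.0812). The MDM2 call was lost without replicate 2 or 3 of 2 µM cytarabine (adjusted p = 0.148 and 0.0936) or replicate 1 or 2 of the switched group (0.0619 and 0.127), with DESeq2 (0.0601) and in the TPM fit (0.45). Other lists were not called at either switch. Interferon-stimulated genes had 12 up and 5 down, and 9 up and 7 down (adjusted p = 0.218 and 0.463). BCL2 family genes had 3 up and 8 down, and 1 up and 5 down (adjusted p = 0.478 and 0.271): BCL2 rose by 0.71 and 0.54, and BCL2L11 and PMAIP1, which promote apoptosis, were at -0.77 and -1.14 after 2 µM and -0.61 and -1.39 after 5 µM. Lysosome and uptake genes had 6 up and 6 down, and 5 up and 7 down (adjusted p = 0.478 and 0.463). FLT3 was at -0.41 ± 0.03 and -0.31 ± 0.03. KMT2A-rearranged leukaemia genes had 7 up and 4 down, and 6 up and 3 down (adjusted p = 0.41 and 0.299). Integrated stress response genes had 5 up and 5 down, and 6 up and 5 down (median -0.04 and -0.07, camera direction up, adjusted p = 0.667 and 0.595). MAPK output genes had 5 up and 5 down (median -0.10, mean 0.24, camera direction down), and 3 up and 5 down (adjusted p = 0.667 and 0.474), and oxidative phosphorylation genes 2 up and 3 down, and none up and 8 down (adjusted p = 0.593 and 0.347). For oxidative phosphorylation after 5 µM, 3 were lower with RLE scaling and 10 in the TPM fit, and after 2 µM 7 in the TPM fit. Among marker lists, neutrophil granule genes had 3 up and 4 down, and 2 up and 4 down (adjusted p = 0.667 and 0.758, the latter with a median of -0.08 and a camera direction of up), and stem and progenitor genes 2 up and 3 down after both (adjusted p = 0.593 and 0.718). Megakaryocyte genes had 1 up and 1 down, and 1 up and none down (adjusted p = 0.864 and 0.798, the latter with a median of -0.11 and a mean of 0.16), and B cell genes 3 down, and 2 down (adjusted p = 0.478 and 0.536). The summed T and NK cell level was 32.6 and 37.3 CPM, the erythroid level 7.81 and 7.04 CPM and the epithelial and fibroblast level 5.15 and 6.78 CPM. The mitochondrial share was 4.50 ± 0.04% and 4.43 ± 0.04%, lower by 0.46 and 0.47 points (exact permutation p = 0.1 each, the smallest possible), and 4 and 6 of the 13 mitochondrial RNAs fell (adjusted p = 0.478 and 0.271; 7 after 2 µM in the TPM fit). Adjusted over the list alone, 12 chaperones rose, 9 BCL2 family, 6 MAPK and 6 stress response genes fell and 2 oxidative phosphorylation genes fell after 2 µM; 9 NF-kB genes rose and 8 cytarabine, 6 stress response and 3 oxidative phosphorylation genes fell after 5 µM; other counts were the same.

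**Figure D3:**
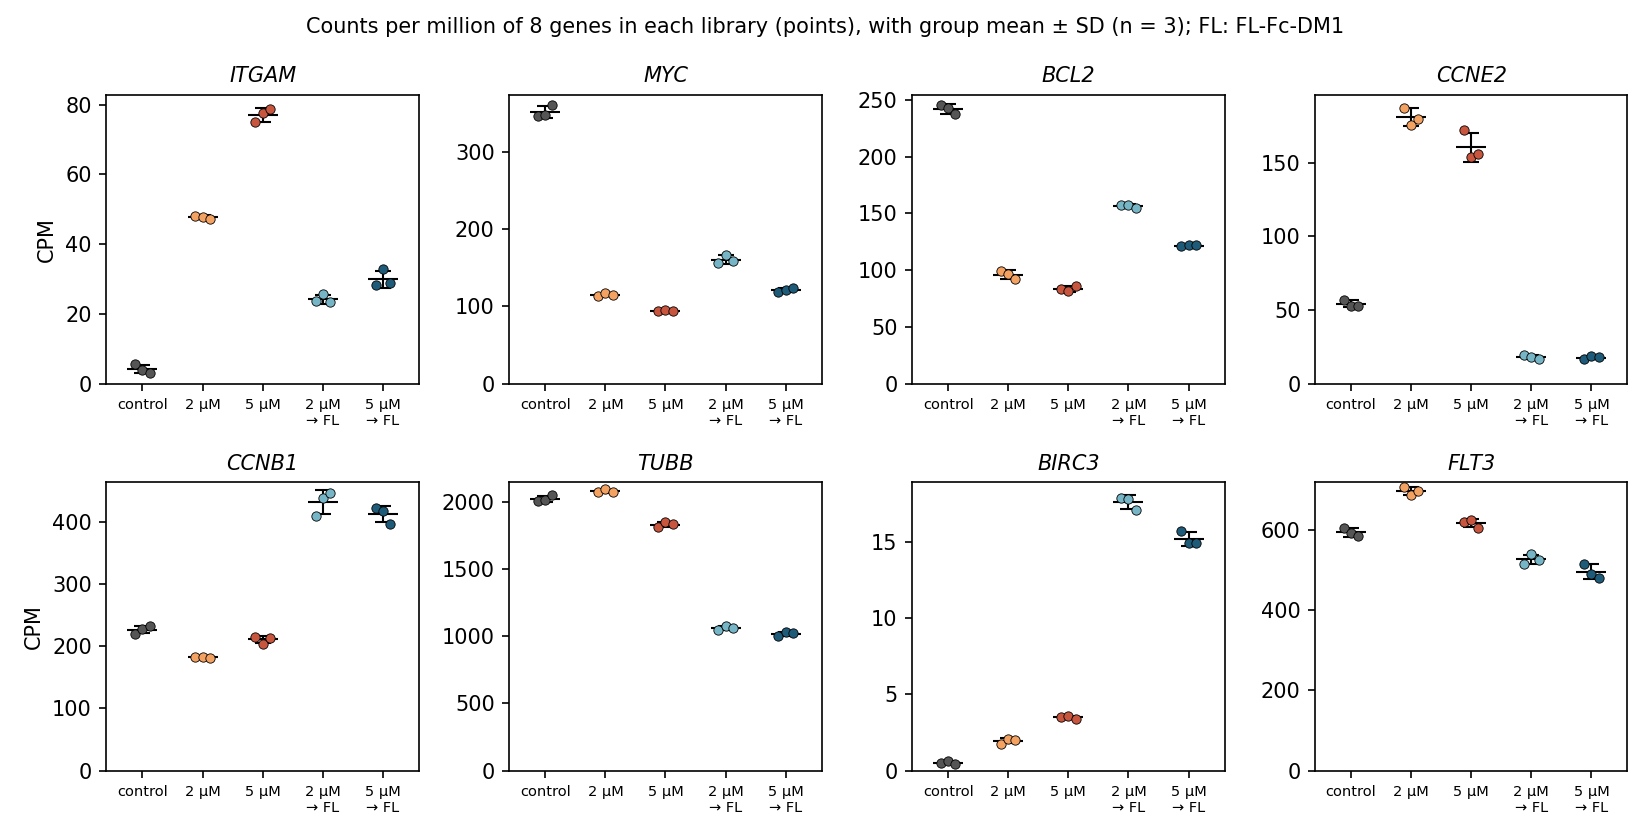
Levels in CPM of ITGAM, MYC, BCL2, CCNE2, CCNB1, TUBB, BIRC3 and FLT3 on linear axes from 0. Each point is a library, and bars give the mean and SD of the 3 libraries of a group.

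The fourth comparison asked whether the switch differed between doses. It differed for 1404 genes. Their log2 change at the switch was higher after 5 µM than after 2 µM in 483 and lower in 921. Higher and lower, or up and down, refer in this comparison to that difference, so a lower value can be a smaller rise. RLE scaling gave 584 higher and 757 lower, the TPM fit 155 and 205, and 14 and 13 differed at least 2-fold. PALD1, a phosphatase-like protein, was higher by 0.88 ± 0.10, TP53I11 by 0.86 ± 0.16 and GNG7 by 0.84 ± 0.17, and IL4I1 was at -1.48 ± 0.14, CCL2 at -1.22 ± 0.17 and BIRC3 at -1.03 ± 0.18. TP53I11 was not called in the TPM fit (adjusted p = 0.925). Of 20 ribosome biogenesis genes none was higher and 18 were lower, or 19 over the list alone (median -0.33, camera adjusted p = 1.27e-23). The median of this list rose at both switches, by 0.73 after 2 µM and by 0.34 after 5 µM. Of 14 chaperones 8 were lower, or 11 over the list alone (median -0.29, camera adjusted p = 2.77e-14). Of 16 NF-kB genes 9 were lower, or 10 over the list alone (median -0.37, camera adjusted p = 1.01e-07). The medians of these lists at the switches after 2 µM and 5 µM were 0.45 and 0.13 for chaperones, and 0.73 and 0.39 for NF-kB genes. Of 12 STAT5 targets 3 were lower (median -0.21, camera adjusted p = 0.00164). Mitosis genes, 4 up and 10 down, or 6 and 14 over the list alone, had a median of -0.08 (camera adjusted p = 0.00294; adjusted p = 0.282 with an estimated correlation). Homologous recombination genes, 3 up and 1 down, had a median of 0.08 (camera adjusted p = 0.00571; adjusted p = 0.282 with an estimated correlation). Cholesterol genes, 6 down, or 7 over the list alone, had a median of -0.08 (camera adjusted p = 0.0208; adjusted p = 0.209 with an estimated correlation), and histones, 2 down, a median of -0.32 (camera adjusted p = 0.0331; adjusted p = 0.122 with an estimated correlation). The histone call was lost with a replicate block (adjusted p = 0.053) and without replicate 2 of 2 µM cytarabine (adjusted p = 0.0504), replicate 3 of 5 µM cytarabine (0.0729) or replicate 1 of the group switched from 2 µM (0.0604), and the cholesterol call without replicate 3 of that group (0.0509). In the TPM fit 11 ribosome biogenesis, 7 chaperone, 6 NF-kB and 3 STAT5 genes were lower. There, 1 mitosis gene was higher and 4 were lower, and no homologous recombination, cholesterol or histone gene was called. With RLE scaling, DNA replication genes (adjusted p = 0.0294, up), interferon-stimulated genes (0.0403, down) and neutrophil granule markers (0.0482, up) were also called, against 0.0537 each with TMM.

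The fifth comparison set the FL-Fc-DM1 groups against control. GPNMB was higher than in control by 6.20 ± 0.10 after 2 µM and 6.86 ± 0.09 after 5 µM, and A2M, a protease inhibitor of plasma, by 5.43 ± 0.11 and 5.85 ± 0.11. BIRC3 rose by 5.07 ± 0.17 after 2 µM and IFI44L, an interferon-induced gene, by 5.39 ± 0.24 after 5 µM. IGLL1 was at -5.08 and -4.85, HPDL at -2.68 and -4.03, ALDH1L2, a mitochondrial folate enzyme, at -2.47 after 2 µM and PRDM8 at -3.20 after 5 µM. After 2 µM 3987 genes rose and 4109 fell, and after 5 µM 4431 rose and 4613 fell, with 837 up and 329 down, and 1226 up and 497 down, at least 2-fold; the TPM fit gave 3783 up and 3143 down, and 4938 up and 3317 down.

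All 16 NF-kB genes rose after 2 µM and 15 rose and none fell after 5 µM (median 1.88 and 1.81, camera adjusted p = 1.35e-18 and 1.22e-09). Of 24 interferon-stimulated genes 20 rose after 2 µM, or 21 over the list alone, and 22 after 5 µM, and none fell (median 1.55 and 2.17, camera adjusted p = 1.95e-11 and 7.35e-15). Of 21 monocyte markers 18 rose and 2 fell in both (median 1.06 and 1.35, camera adjusted p = 1.13e-13 and 6.24e-14), and of 16 lysosome and uptake genes 13 rose and 2 fell in both (median 0.40 and 0.53, camera adjusted p = 8.87e-08 and 5.59e-08). DNA replication genes were 1 up and 28 down, and 0 up and 27 down (median -0.55 and -0.64, camera adjusted p = 3.48e-17 and 5.04e-15), E2F targets 1 up and 20 down in both (median -0.56 and -0.69, camera adjusted p = 1.62e-17 and 6.97e-15) and mitosis genes 24 up and 4 down, and 26 up and 2 down (median 0.33 and 0.40, camera adjusted p = 5.98e-09 and 3.48e-08). Cholesterol genes were 1 up and 15 down, and 0 up and 16 down (median -0.61 and -0.67, camera adjusted p = 5.01e-12 and 8.58e-12). Ribosome biogenesis genes were 2 up and 15 down after 2 µM (camera adjusted p = 0.00347; adjusted p = 0.0953 with an estimated correlation) and 19 down after 5 µM (camera adjusted p = 9.94e-11). Tubulins were 1 up and 7 down after 2 µM (camera adjusted p = 1.83e-04; adjusted p = 0.0508 with an estimated correlation), and 1 up and 8 down after 5 µM, or 2 and 8 over the list alone (camera adjusted p = 1.45e-04).

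The other list calls of this comparison were lost with an estimated correlation. Oxidative phosphorylation genes were 15 down and 18 down (camera adjusted p = 0.00192 and 4.19e-04; adjusted p = 0.306 and 0.275 with an estimated correlation), with none up. Homologous recombination genes were 1 up and 14 down, and 1 up and 15 down (camera adjusted p = 1.98e-04 and 0.0121; adjusted p = 0.105 and 0.262 with an estimated correlation). Genes of cytarabine transport and metabolism were 2 up and 7 down, and 4 up and 8 down (camera adjusted p = 0.0135 and 0.00669; adjusted p = 0.124 and 0.0929 with an estimated correlation). Neutrophil granule markers were 2 up and 5 down after 2 µM (camera adjusted p = 0.0114; adjusted p = 0.131 with an estimated correlation). After 5 µM histones were 7 up and 1 down (camera adjusted p = 0.0312; adjusted p = 0.0731 with an estimated correlation) and chaperones 4 up and 10 down (camera adjusted p = 0.00669; adjusted p = 0.059 with an estimated correlation). Over the 8 contrasts, in the order cytarabine at 2 µM and 5 µM, dose, switch after 2 µM and 5 µM, FL-Fc-DM1 groups against control and interaction, 11, 10, 11, 12, 12, 14, 15 and 8 lists were called, and 8, 7, 8, 9, 12, 8, 10 and 4 of these calls held with an estimated correlation.

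The last comparison asked how far changes were shared and how far they turned back. Of 12448 genes, 4073 rose at both cytarabine doses, where 1675 would by chance, 3738 fell at both, where 1400 would, and 4 and 15 went opposite ways. The log2 fold changes of the doses correlated at 0.93 across genes; simulations without effect gave 0.51, because the doses share the 3 control libraries. The covariance was 0.583, against 0.0378 in the simulations. At the switches, which share no library, 2902 genes rose in both, where 1092 would by chance, 3025 fell in both, where 1170 would, and the correlation was 0.79. Of the 8579 genes changed by 2 µM cytarabine, 3894 (45.4%) moved back at the switch after 5 µM and 1419 (16.5%) moved further, where 2415 and 2409 would by chance, with a correlation of -0.32. Of the 8905 genes changed by 5 µM, 4494 (50.5%) moved back at the switch after 2 µM and 1704 (19.1%) moved further, where 2879 and 2876 would by chance, with a correlation of -0.27. Of those changed at least 2-fold by cytarabine, 685 of 1347 and 860 of 1707 moved back by any amount that was called, where 384 and 554 would by chance. MYC, BCL2 and ribosome biogenesis genes moved back toward control, while CCNE2 fell from above control, 54.1 CPM, to below it.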

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

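The tests of scaling, of a return to control levels and of tubulin mRNA decay were chosen after the results were seen; the tests of other G2/M genes, of summed tubulins and of depth were not.

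A test of the difference between the switches after 2 µM and 5 µM cytarabine singled out 1404 of 12448 genes (11.3%) and 8 gene lists. It also called 35 of a set of 71 genes, not all of them named above. That set holds the extremes of this same difference, so its share cannot be compared with that of all genes. The median differences (5 µM minus 2 µM, log2) were -0.37 for NF-kB genes, -0.33 for ribosome biogenesis genes, -0.32 for histones, -0.29 for endoplasmic reticulum chaperones, -0.21 for STAT5 targets, -0.083 for mitosis genes, -0.079 for cholesterol genes and 0.078 for homologous recombination genes. With an estimated correlation 4 of the 8 list calls were lost, mitosis (adjusted p = 0.282), homologous recombination (0.282), cholesterol (0.209) and histones (0.122). A positive difference means a higher log2 change at the switch after 5 µM than after 2 µM. It was found for PALD1 (0.88), TP53I11 (0.86), GNG7 (0.84), SUCNR1 (0.46), BRIP1 (0.40) and E2F8 (0.32). Smaller ones were found for MS4A7 (0.29), FANCI (0.26), PCNA (0.19), MKI67 (0.13) and TUBB (0.12). The log2 changes of TP53I11, SUCNR1, BRIP1, E2F8, FANCI, PCNA, MKI67 and TUBB were negative at both switches, and less so after 5 µM. Among NF-kB and inflammatory genes, the differences were -1.03 for BIRC3, -1.22 for CCL2, -0.43 for NFKBIA and -0.20 for NFKB1. Among mitosis genes and histones they were -0.28 for CCNB1, -0.29 for PLK1, -0.45 for CENPE, -0.48 for CDC20, -0.54 for H2AC6 and -0.55 for H2BC12. The remaining values were -1.48 for IL4I1, -0.81 for CYP1B1, -0.47 for C3, -0.39 for ITGAM, -0.22 for CALR, -0.31 for HYOU1, -0.44 for HSPA5, -0.42 for XBP1, -0.34 for WDR43, -0.48 for UTP20, -0.42 for PIM1, -0.59 for IL2RA, -0.44 for SLC7A11 and -0.16 for BCL2.

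Of 100 splits of the 12 libraries, 7 including the real one gave as many genes for this difference, so chance cannot be excluded by the splits. The real split gave 1620 genes in a fit of these libraries alone and the highest other gave 2170. The 6 other splits had every switched library at the exchanged dose and 4 of 6 cytarabine libraries at their own dose, so they carry the effect of dose itself.

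The group comparisons with 3 against 3 libraries have 10 splits, too few for a share under 0.05. As many genes came from 1 of 10 splits, the real one, in each of the 7. In the order cytarabine at 2 µM and 5 µM against control, 5 µM against 2 µM, the switches after 2 µM and 5 µM, and the FL-Fc-DM1 groups against control, the real splits gave 8368, 8651, 2576, 8219, 6989, 7765 and 8749 genes. The highest other split gave 1 gene for 5 µM against 2 µM and 0 for the rest.

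At the switch, most mitosis genes were higher while E2F and replication genes were lower. Of 30 mitosis genes 21 rose and 8 fell after both doses, and MKI67, a member of this list, was at -0.52 and -0.39. With TMM, RLE and log2(TPM + 1), the mitosis median was 0.35 or more and the E2F and replication medians -0.59 or less at both switches. The pattern thus did not depend on which of these was used. They moved the medians little, so they cannot decide on other scalings or on a change in total RNA. The mitosis list was also above control, by 0.33 after 2 µM and 0.40 after 5 µM, which argues against a return that stops at control levels. A return that overshoots control after cytarabine is removed was not tested, as no group had removal alone. Another 20 G2/M genes, listed before their values were seen, had medians of 0.35 after 2 µM (15 up, 4 down) and 0.27 after 5 µM (14 up, 2 down). A larger share of cells in late G2 or mitosis would give such medians, but leaves the members that fell unexplained. Such a shift may therefore be the biology behind the pattern, as a hypothesis: DM1 blocks microtubules, but the removal of cytarabine happened at the same time and was not tested apart.

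TUBB and TUBA1B were lower at both switches. Summed over near-identical genes, alpha- and beta-tubulins were lower by log2 ratios between -0.53 and -0.79, which argues against reads moving between paralogs. With every library thinned to 13588481 counts or fewer, TUBB was at -0.97 after 2 µM and -0.85 after 5 µM, but a gene this abundant hardly moves when thinned, so this decides nothing on depth. Library totals were 13588481 to 15093186 counts in 5 µM cytarabine and 13965381 to 15766274 after the switch. These ranges overlap, while TUBB was at 1813 to 1852 CPM in 5 µM cytarabine and 1003 to 1033 CPM after the switch. For TUBB in these libraries this argues against depth. Of 7 tubulins at 10 CPM or more, 4 fell at both switches (TUBA1A, TUBA1B, TUBA4A and TUBB). Decay of tubulin mRNA when free tubulin rises, a known response to agents that depolymerise microtubules, may contribute, but 4 of 7 members cannot be told apart from a fall of single genes for other reasons.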

How the results depend on the processing

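Thinning of replicate 2 of 2 µM cytarabine and leaving out libraries for lists and sharing were chosen after the data were seen. With RLE scaling, both filters, DESeq2, thinning, fits of only the groups compared and the replicate block, counts of genes, called lists and shared genes stayed within 1.5 times of their values wherever these were run. At an absolute log2 fold change of at least 1, the counts in the order of contrasts given in the report were 1347, 1707, 58, 901, 676, 1166, 1723 and 27, with sharing of 1223 and 486 genes and reversal of 248 and 334 where both changes had to reach it; fewer genes pass by construction. In the limma-trend fit on log2(TPM + 1), which changes scaling, pseudocount and test together, 1041 genes changed between the doses and 360 in the interaction; the cause was not tested. With fry, which tests whether members move on balance one way, 23 and 24 lists were called at the cytarabine doses, 23 and 23 at the switches and 24 and 26 in the FL-Fc-DM1 groups. With an estimated correlation 8 lists were called after 2 µM against control and 4 in the interaction; the cause was not tested.

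Leaving out 1 library at a time gave 7991 to 8256, 8511 to 8648, 1571 to 1907, 7387 to 7651, 6390 to 6591, 7569 to 7784, 8634 to 8798 and 1062 to 1287 changed genes, 11 to 13, 10 to 11, 10 to 13, 12 to 12, 12 to 12, 14 to 14, 15 to 15 and 7 to 12 called lists, sharing of 7395 to 7604 and 5523 to 5753 genes, and reversal of 3617 to 3868 and 4185 to 4447. Of 978 tests of the 93 called lists, 941 were the same, 37 weaker (27 of them with an estimated correlation) and none reversed. Of 6855 tests of 490 gene results, 6793 were the same, 55 weaker, 3 stronger and 4 reversed. DESeq2 gave no adjusted p for TP53I11, BIRC3 and CCL2 in the interaction. Values that changed sign were TUBA1B at 2 µM (0.0079 with limma-trend on log2(TPM + 1)), ATP5PB at the switch after 2 µM (-0.059, also with limma-trend) and KRT8 there, which was not called (-0.039 to 0.024 with 1 library left out); the cause was not tested.

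Same-number libraries correlated best with each other in 3 of 10 pairs of groups, a hint from the data and not the design. These were the pairs among control, 2 µM and 5 µM cytarabine. No pair with an FL-Fc-DM1 group had this pattern, and same-number correlations there were -0.0377 to 0.0840. Whether the FL-Fc-DM1 libraries were handled apart from the others was not tested, and it cannot be told apart from the switch. The replicate block gave 8738, 9027, 2616, 8225, 7209, 8256, 9180 and 1658 changed genes, ended the histone call of the interaction (adjusted p = 0.053) and ended no other list call. It added calls of neutrophil granule markers at both doses and after the switch from 5 µM against control (adjusted p = 0.0326, 0.0379 and 0.0381) and of stress response genes at 2 µM (0.0492). Depth limits genes near the floor of 0.0986 to 0.221 CPM.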

Other observations

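The pathways below were chosen after the data were seen, from 325 KEGG pathways named in the file and tested with camera.

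With cytarabine 85 of the 325 pathways were called at 2 µM and 81 at 5 µM, and 26 and 46 of these held with an estimated correlation. Among the 4 pathways given here, 3 complement and 6 adhesion genes are also in the fixed lists, and no aminoacyl-tRNA or proteasome genes are. Of 44 aminoacyl-tRNA biosynthesis genes, which charge tRNAs for translation, 2 rose and 38 fell at both doses (median -0.41 and -0.54, camera adjusted p = 2.48e-11 and 8.82e-11; adjusted p = 0.0324 and 0.0172 with an estimated correlation). Of 37 genes of the complement and coagulation cascades, 33 rose and 2 fell at 2 µM, and 32 rose and 2 fell at 5 µM (median 1.03 and 1.28, camera adjusted p = 1.33e-10 and 1.04e-11; adjusted p = 0.0314 and 0.00342 with an estimated correlation). Of 74 cell adhesion molecules, 47 rose and 10 fell, and 49 rose and 7 fell (median 0.77 and 0.89, camera adjusted p = 3.97e-08 and 7.04e-09; adjusted p = 0.0252 and 0.00258 with an estimated correlation). Of 44 proteasome genes, 1 rose and 39 fell at both doses (median -0.30 and -0.33, camera adjusted p = 6.55e-06 and 8.59e-06; adjusted p = 0.204 and 0.166 with an estimated correlation).

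At the switch to FL-Fc-DM1, 3 of 22 mismatch repair genes, 9 of them in the fixed lists, rose and 16 fell after 2 µM, and 3 rose and 17 fell after 5 µM (median -0.47 at both, camera adjusted p = 2.87e-09 and 1.40e-09; adjusted p = 0.0152 and 0.0201 with an estimated correlation). Proteasome genes, 34 up and 4 down after 2 µM, had a median of 0.23 (camera adjusted p = 0.0044; adjusted p = 0.654 with an estimated correlation). After 5 µM, 20 proteasome genes rose and 7 fell, with a median of 0.09 (adjusted p = 0.565). Of 14 pathways called after 2 µM and 21 after 5 µM, 1 and 4 held with an estimated correlation. In KEGG homologous recombination 11 of 39 genes rose and 23 fell after 2 µM, and 5 rose and 22 fell after 5 µM. With an estimated correlation, its camera adjusted p was 0.198 and 0.099, and that of Fanconi anemia 0.254 and 0.161. It was 0.137 and 0.0277 for DNA replication, and 0.0806 and 0.099 for ribosome biogenesis.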
